A study of Mus musculus with 21 samples.

How the data were processed

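RNA from mouse MIN6m9 cells, a subclone of an insulinoma-derived beta cell line, was hybridised to 21 one-colour Agilent expression arrays in 2 experiments. In the fatty acid experiment, cells received palmitate or oleate at 400 uM for 48 h, or neither, with 3 arrays per group. In the PERK experiment, cells carrying Fv2E-PERK, a PERK kinase that dimerises on addition of the small molecule AP20187, received 1 nM AP20187 for 6, 12, 24 or 48 h or a mock treatment, and wild-type cells received the mock treatment, with 2 arrays per group. The harvest times of the untreated and mock cells are not given in the sources used here, and wild-type cells with AP20187 are not analysed here. Groups and replicate numbers were taken from the sample titles. For 1 wild-type mock array the title and the source name carry different replicate numbers, and the title was used. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

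Per the labels, RNA was amplified and labelled with Cy3 by a low-input kit. Per the file headers, the spot intensity values were extracted by the authors with Agilent Feature Extraction 10.7.1.1, which subtracted the background, removed a spatial trend and set a floor, without scaling between arrays. The deposited files also hold the raw median intensity of each spot and of its local background, and flags for spots that were saturated, were outliers or lay well above background. The column of mean spot intensity is not used here, so the normexp alternative was run on the median intensity instead. The deposited series matrix holds log2 values whose processing is not given in the sources used here. Set against the scanner values, they are log2 of the processed signal minus 1 constant per array and 1 baseline per probe and experiment. In the PERK experiment that constant equals the array's 75th percentile to within 0.002. In the fatty acid experiment it differs from it by -0.49 to 0.19, and 10480 to 17661 of 55681 probes per array are blank, with signals of at most 4. What the baseline was and why the constants differ stays unknown; the direction and log base follow from the comparison. The medians of the matrix columns are 0.26, 0.01 and -0.26 for untreated replicates 1 to 3, 0.35, -0.13 and -0.18 for oleate, and -0.27, -0.23 and -0.26 for palmitate. They are 0.12 and 0.09 for wild-type mock, 0.19 and 0.33 for Fv2E-PERK mock, -0.25 and -0.12 at 6 h, -0.28 and -0.20 at 12 h, -0.32 and -0.14 at 24 h, and -0.20 and -0.18 at 48 h.

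Each array carries 59305 spots for 55681 probes and 3671 control spots, which were left out. Probes were named by matching their unversioned accessions to a RefSeq gene table of mouse assembly GRCm38.p6. A symbol was found for 26582 probes and none for 29099, of which 16194 are named only by mm9 coordinates and 523 by RefSeq mRNA accessions without a match. Unnamed probes stayed in the tests under their own identifiers. Outlier spots were left out, 142 to 379 per fatty acid array and 108 to 199 per PERK array; 0 spots were saturated. The processed signal was averaged over the spots of a probe, taken to log2, and reduced by the array's 75th percentile. The signal at that percentile was 336 to 459 in the fatty acid experiment and 380 to 823 in the PERK experiment, against a median local background of 18 to 19 and 22 to 26. The share of probes well above background was 49.8 to 53.5% and 46.8 to 56.9%. For each of 5370 symbols with over 1 probe, the probe with the highest mean over all 21 arrays stood for the gene, which left 37208 entries with 20145 symbols. A second probe of the gene was called in the opposite direction for Bcan, Ccnb1 and Cpt2 at 48 h against 6 h, Cdkn1a at 6, 12 and 24 h, Elovl1 at 48 h and Trp53inp1 at 6 h. Entries were tested in an experiment if well above background on all arrays of at least 1 of its groups. Where a gene was well above background on no array of a group, only a bound on its fold change is given: the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Where such genes move the median of a list, it is also given with each at its bound and genes dim in both groups left out.

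Each experiment was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 1 coefficient per group, and p-values were adjusted by the Benjamini-Hochberg method over all entries tested in a contrast. Errors of log2 changes are standard errors from that fit unless marked SD. A gene rose or fell where the adjusted p was under 0.05. The contrasts were palmitate and oleate against untreated, palmitate against oleate, each AP20187 time against mock Fv2E-PERK cells, 48 h against 6 h, and Fv2E-PERK against wild-type mock. For the overlap of the experiments, palmitate-raised genes were higher than in untreated and in oleate-treated cells. AP20187-raised genes passed an F test over the 4 times and were higher at 24 h or 48 h, and lowered genes were defined likewise. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 20 lists of a contrast. Where a range of adjusted p is given for a list, it runs over all alternatives, fry included. Fry compares no list with other genes, so the low end of a range can be fry's and not camera's. The lists hold integrated stress response (ISR) transcription factors and ATF4/CHOP targets, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, endoplasmic reticulum (ER) chaperones and ER-associated degradation, beta cell identity, sterol synthesis, fatty acid synthesis, fatty acid oxidation and lipid droplets, NRF2 targets, NF-kB and chemokine genes, and interferon-stimulated genes. The others hold cell cycle, apoptosis, p53 targets, immediate early genes, oxidative phosphorylation, glycolysis with genes usually low in beta cells, other islet endocrine cells, exocrine cells, and mesenchymal, endothelial and immune cells. Of their genes, Pycr1, Mx1, Amy2b and Cd68 had no named probe.

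The groups, contrasts, lists, first set of alternatives and the rule for named genes were fixed before the data were examined. In each contrast the text names the 10 largest rises and falls (5 for each AP20187 time) among called genes with every array of the higher group above every array of the other, up to 4 called members of each list with the largest changes, and the 10 genes shared between experiments with the largest smaller change. Members with the highest signal stand in for a list with too few calls. Eif2ak3, Ins1, Ins2, Ddit3, Atf3, Trib3 and Asns are followed in every sample. Of these, the text gives the ones that carry the description. The values of 1 list member are not reported here, and it stays in the fits, counts and list tests. Lists of 20 skeletal muscle and 16 heart muscle genes were written after the muscle genes among the largest changes had been seen and before their own members were looked at. The 9 heart muscle genes seen first form a list of their own.

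The alternatives were normexp background correction with an offset of 50, quantile normalization, the series matrix values, 2 other filters on dim probes, every probe as its own entry, all 21 arrays in 1 fit, only the 2 groups compared, the replicate number or the slide as a block, another variance prior, a 2-fold threshold, and leaving out each array in turn. Chosen after seeing the data were scaling to 7 spike-in probes, leaving out palmitate replicates 1 and 2, leaving out local spot defects on tiles of 8 by 8 spots, and fits on 1 slide alone. Slides were read from the file headers: slide 1 held the untreated and oleate arrays and palmitate replicates 1 and 2, slide 2 palmitate replicate 3, slide 3 the wild-type mock and 48 h arrays, and slide 4 all others.

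The steps were tested on simulated data made from the real arrays' means and spreads, with 50 genes changed at each size. For palmitate against untreated, simulated on 20935 genes, 8% of genes changed by 0.25 log2 units were called, 40% at 0.5, 88% at 1 and 96% at 2. For AP20187 at 24 h against mock, on 23376 genes, the shares were 2, 34, 58 and 92%. In those 2 runs 0 genes were called in the wrong direction, and 8 and 6 unchanged genes were called, 5.88 and 5.83% of calls. A list of 20 genes shifted by 0.5 passed camera in both runs (p = 1.9e-44 and 1.2e-33; p = 4.9e-06 and 1.2e-05 with an estimated correlation), and 2 and 3 of 200 unchanged lists had a p under 0.05. Genes were simulated independently of one another, so these 2 runs cannot show how often camera calls unchanged lists of correlated genes. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and data.table in version 1.17.8, and random blocks used statmod 1.5.0. For the slide test, 10 simulations used the observed group means with the wild-type mock mean set to that at 48 h, so that only the slides differ.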

Results

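Gene expression was measured on 21 arrays in a beta cell line under 2 kinds of treatment. The first asked which genes a saturated fatty acid induces. MIN6m9 cells, which make and secrete insulin, were left untreated or given 400 uM palmitate or oleate for 48 h (n = 3 arrays each). The second asked which genes follow the integrated stress response (ISR), the programme that starts when a kinase such as PERK phosphorylates eIF2alpha. Cells with the drug-activated kinase Fv2E-PERK were given 1 nM AP20187 for 6, 12, 24 or 48 h (n = 2 arrays each). Signals are log2 values relative to the array's 75th percentile. Between 46.8 and 56.9% of probes per array were well above background. In the fatty acid experiment 21279 entries were tested and in the PERK experiment 23386, and the number of arrays limits the precision. Replicates correlated at 0.978 to 0.996 across genes, which are not independent replicates. The SD of the log2 difference between replicates was 0.290 to 0.390, except for untreated replicate 2, which differed from the other untreated arrays by 0.687 and 0.668.

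Insulin transcripts were the first reference in each experiment. Ins1 and Ins2, the mouse insulin genes, had signals of 9.77 ± 0.18 and 8.86 ± 0.19 (SD, n = 3) in untreated cells, and 9.69 ± 0.06 and 8.84 ± 0.16 with palmitate. Neither passed the test against untreated (log2 change -0.08 ± 0.09 and -0.02 ± 0.11). Eif2ak3, which encodes PERK, changed by 0.09 ± 0.08 with palmitate and did not pass. In Fv2E-PERK cells Eif2ak3 differed from wild-type by -0.12 ± 0.15, without passing. Whether its probe covers the introduced kinase is unknown, so it checks nothing about the labels.

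The comparison of palmitate with untreated cells asked which genes the saturated fatty acid changes. ISR genes rose together: 18 of 22 rose and 0 fell, the same numbers when adjusted over the list alone, with a median change of 0.91 log2 units, or 0.80 with genes dim in untreated cells at their bound. Atf3, a stress-induced transcription factor, rose by 2.62 ± 0.09 (n = 3 and 3) and Nupr1, a stress-induced chromatin protein, by 1.41 ± 0.07. Trib3, a pseudokinase induced by ATF4 and CHOP, rose by 1.39 ± 0.08, and Ddit3, which encodes CHOP, by 1.00 ± 0.07. Slc7a11, the cystine transporter, and Fgf21, a stress-induced hormone, were well above background on no untreated array and were at least 3.85-fold and 1.67-fold higher with palmitate. For Fgf21 this depends on the processing: the call was lost with normexp (a log2 change of 0.39) and the direction turned to -5.38 in the series matrix values. Genes of amino acid synthesis and transport rose in 17 of 22 cases (19 adjusted over the list alone) with a median of 0.68. They were led by Cth, which makes cysteine, at 2.31 ± 0.05, the cationic amino acid transporter Slc7a3 at 2.24 ± 0.08 and the glycine transporter Slc6a9 at 1.59 ± 0.05. Of 20 cytosolic aminoacyl-tRNA synthetases 13 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.34, which was 0.11 in the series matrix values, and Nars at 0.65 ± 0.07. Asns, asparagine synthetase, rose by 0.61 ± 0.13, a call that was lost without untreated replicate 3 and without palmitate replicate 3. It was also lost with slide as a fixed block. Only palmitate replicate 3 lay on slide 2, so that block amounts to leaving this array out and is no separate check. Camera called these 3 lists higher (adjusted p = 1.3e-19, 5.8e-19 and 8.7e-08), and each held at adjusted p = 0.011 with an estimated correlation.

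**Figure D1:**
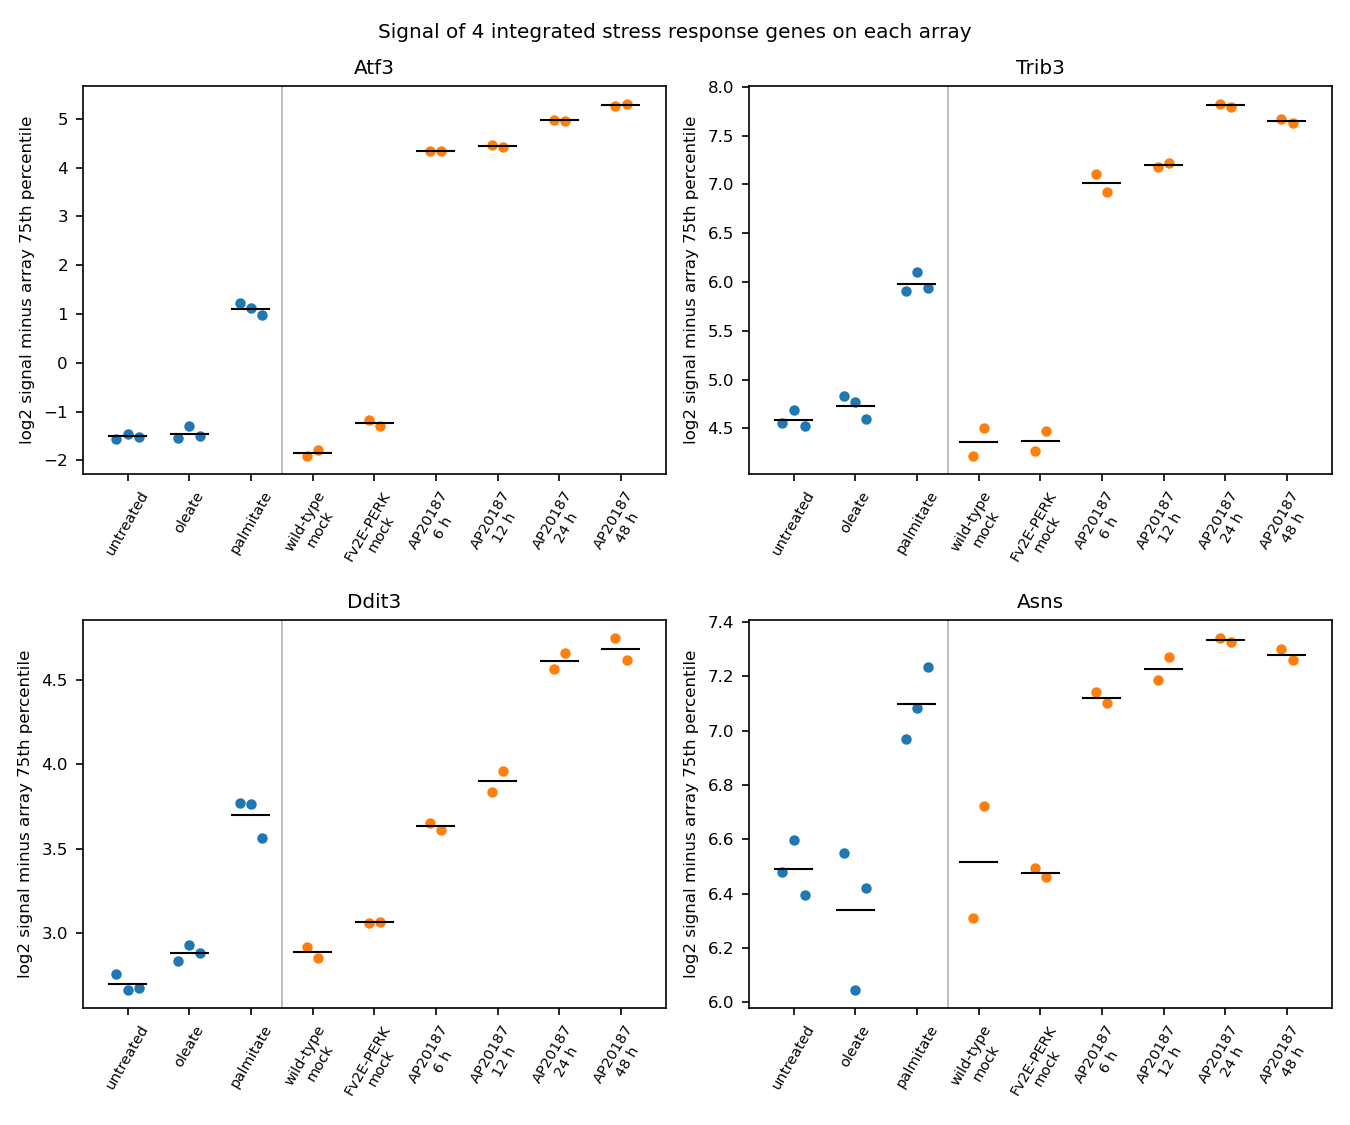
Signal of Atf3, Trib3, Ddit3 and Asns (vertical axes, log2 minus the array's 75th percentile) on each of the 21 arrays, by group; each point is 1 array, the black line is the group mean, blue marks the fatty acid and orange the PERK experiment. Atf3 averages -1.51 in untreated, -1.45 in oleate and 1.11 in palmitate arrays, and -1.24 in mock Fv2E-PERK arrays against 4.34 to 5.28 with AP20187.

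Lipid genes changed as well. Sterol synthesis genes rose in 15 of 20 cases with 0 falls (17 and 0 adjusted over the list alone; median 0.60). The sterol enzyme Msmo1 rose by 1.01 ± 0.08. Camera gave adjusted p = 1.1e-13, and adjusted p = 0.036 with an estimated correlation. Fatty acid synthesis genes rose in 8 of 15 cases and 1 fell (9 and 1 adjusted over the list alone; median 0.27), among them Scd1, the stearoyl-CoA desaturase, at 1.05 ± 0.08 (camera adjusted p = 2.8e-04, adjusted p = 0.17 with an estimated correlation). Of 23 genes of fatty acid oxidation and lipid droplets 9 rose and 1 fell (11 and 2 adjusted over the list alone; median 0.19, which was 0.12 with normexp and turned to -0.04 in the series matrix values). In those matrix values the sterol and fatty acid synthesis medians were 0.37 and 0.05. Cpt1a, which carries long-chain fatty acids into mitochondria, rose by 1.70 ± 0.05, and Fabp3, a fatty acid binding protein abundant in heart, fell by 1.51 ± 0.09 (camera adjusted p = 1.5e-04, adjusted p = 0.12 with an estimated correlation). Heart muscle transcripts were also low on the palmitate arrays, as described below, and whether the fall of Fabp3 shares their cause was not tested.

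Genes of cell division fell: 15 of 23 fell and 0 rose (16 and 0 adjusted over the list alone; median -0.27, or -0.50 in the series matrix values and -0.15 with spike-in scaling). Birc5, needed for chromosome segregation, fell by 0.58 ± 0.06, and Cdc20, which activates the anaphase-promoting complex, fell by 0.53 ± 0.05 (camera adjusted p = 3.6e-07, adjusted p = 0.10 with an estimated correlation). Among 12 p53 targets 6 rose and 2 fell (7 and 4 adjusted over the list alone; median 0.27, or 0.05 in the series matrix values), with Phlda3 at 1.12 ± 0.06 and the cell cycle inhibitor Cdkn1a at 0.92 ± 0.09 (camera adjusted p = 0.0031, adjusted p = 0.13 with an estimated correlation). Of 30 beta cell identity genes 8 fell and 1 rose, the same adjusted over the list alone, with a median of -0.14. Over the genes of the list test the median was -0.16, -0.37 in the series matrix values and -0.04 with spike-in scaling. Slc2a2, the glucose transporter GLUT2, fell by 1.62 ± 0.21 and Glp1r, the GLP-1 receptor, by 0.56 ± 0.07. Camera called that list lower (adjusted p = 0.0094), a call lost with quantile normalization (0.098), with normexp (0.053), in the series matrix values (0.68) and with an estimated correlation (adjusted p = 0.34). Over all its alternatives, fry among them, the adjusted p ran from 5.2e-04 to 0.68, and the ranges given below for other lists were taken likewise. Of 10 NF-kB and chemokine genes 5 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.42, or 0.16 with normexp). The chemokine Cxcl10 was at least 1.45-fold higher, a call lost with normexp, and the NF-kB subunit Relb rose by 0.57 ± 0.08 (camera adjusted p = 0.0038, lost in the matrix values at 0.070 and with an estimated correlation at adjusted p = 0.094, within a range of 5.3e-04 to 0.094).

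ER chaperone genes moved little: 5 of 26 rose and 1 fell, the same adjusted over the list alone, with a median of 0.09 that turned to -0.14 in the series matrix values. Herpud1, which acts in ER-associated degradation, rose by 0.48 ± 0.06 and Derl2, of the same pathway, fell by 0.32 ± 0.05 (camera adjusted p = 0.0078, lost in the matrix values at 0.20 and with an estimated correlation at adjusted p = 0.22, within a range of 6.8e-05 to 0.22). Of 20 oxidative phosphorylation genes 4 fell (6 adjusted over the list alone; median -0.13, or -0.36 in the matrix values and -0.01 with spike-in scaling), with Cox5a, a subunit of cytochrome c oxidase, lower by a log2 change of -0.35 ± 0.05. Camera gave adjusted p = 0.0037, lost without palmitate replicates 1 and 2 (0.19), in the series matrix values (0.20), with spike-in scaling (0.075) and with an estimated correlation (adjusted p = 0.34), within a range of 5.6e-04 to 0.34. Of 13 interferon-stimulated genes 5 rose and 2 fell (median 0.01, negative with normexp, in the matrix values and without palmitate replicates 1 and 2). Of 16 apoptosis regulators 4 rose (5 adjusted over the list alone), with a median of -0.01 that was positive with quantile normalization, normexp and spike-in scaling, as was camera's direction. Of 8 mesenchymal, endothelial and immune markers 1 rose (median 0.16, -0.07 in the matrix values). Camera gave these lists adjusted p = 0.041, 0.038 and 0.041, and none kept its call with an estimated correlation (adjusted p = 0.28, 0.12 and 0.13). These calls were also lost without palmitate replicate 1 (0.13, 0.056 and 0.12) and without replicates 1 and 2 (0.19, 0.15 and 0.35), and each under further alternatives, within ranges of 0.0056 to 0.28, 4.4e-04 to 0.15 and 0.0095 to 0.35. Exocrine markers, of which 4 were measured and 2 rose (3 adjusted over the list alone; median 0.25), had adjusted p = 0.0070, and the call was lost with no filter on dim probes and with an estimated correlation (adjusted p = 0.12). Spp1, osteopontin, rose by 1.05 ± 0.11. NRF2 targets (3 rose and 2 fell of 16), immediate early genes (2 rose of 11; 3 rose and 3 fell adjusted over the list alone), glycolysis genes (1 rose and 1 fell of 14; 1 and 0 adjusted over the list alone) and other islet endocrine markers (2 rose and 2 fell of 7) did not pass (adjusted p = 0.25, 0.31, 0.25 and 0.67). Counts adjusted over the list alone were the same where none are given. The ranges of adjusted p given above include fry. Among their members, Nqo1, a quinone reductase, fell by 0.79 ± 0.05, and Ppy, pancreatic polypeptide, rose by 1.34 ± 0.09.

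In total 4267 entries changed with palmitate, 1577 higher (37.0%) and 2690 lower, and 286 of them changed at least 2-fold. The count was 2670 without palmitate replicate 1. Scaling to spike-in probes raised every gene, and so every list median, by 0.12 log2 units relative to this scale. It left far fewer calls, of which 81.8% were higher. The series matrix values moved the median of all genes by -0.23. Acox2, a peroxisomal oxidase of branched acyl chains, was well above background on no untreated array and was at least 21.8-fold higher. Car6, a secreted carbonic anhydrase, rose by 5.30 ± 0.26, Ostn, osteocrin, by 4.19 ± 0.14, the galectin Lgals3 by 3.28 ± 0.09, Saa3, an acute-phase protein, by 3.17 ± 0.18 and Anxa10 by 3.07 ± 0.09. Ptgs2, the inducible cyclooxygenase, was at least 3.18-fold and Akr1b7, an aldo-keto reductase, at least 5.48-fold higher.

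Muscle transcripts set the palmitate arrays apart in these same contrasts, beside every gene group named for palmitate. The largest falls were heart muscle genes: the cardiac troponins Tnnt2 and Tnni3 were at least 40.2-fold and 37.8-fold lower than in untreated cells and the myosin-binding protein Mybpc3 at least 17.6-fold, and Myh6, a cardiac myosin heavy chain, fell by 6.23 ± 0.16. The median signal of the 9 heart muscle genes was 0.11 to 0.57 on the untreated arrays and -0.49 to 0.50 on the oleate arrays, against -6.86 to -6.69 on the palmitate arrays. It was -6.34 and -6.42 on the wild-type mock arrays of the other experiment. Palmitate replicates 1 and 2 also carried skeletal muscle transcripts: over 20 skeletal muscle genes the median signal was -1.53 and -1.28 there and -6.28 on palmitate replicate 3. Tnni2, a fast skeletal troponin, was among the 10 largest rises (3.59 ± 1.02) on account of those arrays. With replicates 1 and 2 left out, a choice made after seeing the data, 1719 entries changed with palmitate against untreated. Of these, 1367 were among the 4267 and in the same direction. Palmitate replicate 3 is then assumed to vary like the other groups. It was also the only array on slide 2, while the untreated and oleate arrays lay on slide 1. Slide and palmitate therefore cannot be told apart in this check. The ISR list then had a median of 0.79, against 0.82 with all palmitate arrays over the same genes, and the amino acid list had 0.68 both ways.

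**Figure D2:**
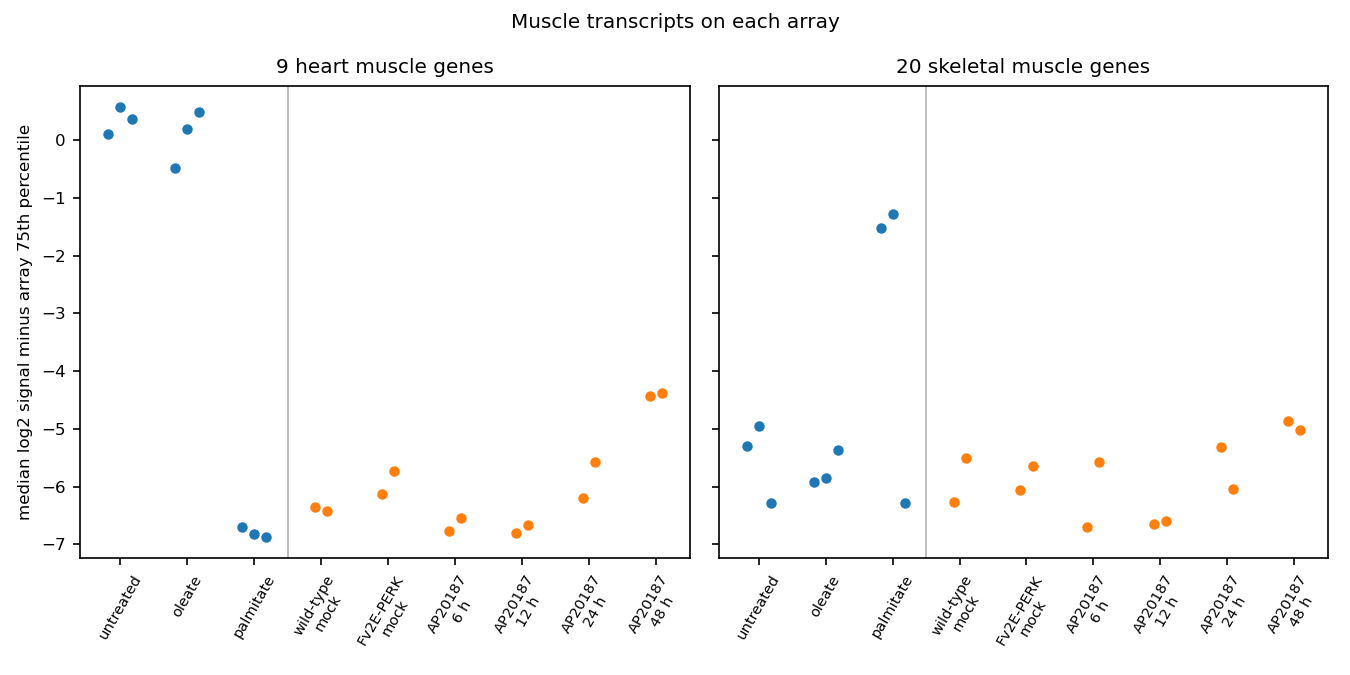
Median signal (vertical axes, log2 minus the array's 75th percentile) of 9 heart muscle genes, left, and 20 skeletal muscle genes, right, on each of the 21 arrays, by group; each point is 1 array, blue for the fatty acid and orange for the PERK experiment. The heart genes lie between -0.49 and 0.57 on untreated and oleate arrays only, and the skeletal genes lie at -1.53 and -1.28 on palmitate replicates 1 and 2.

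Oleate, compared with untreated cells to ask what a monounsaturated fatty acid does at that dose and time, changed 178 entries, 71 of them higher (39.9%), with 9 changed at least 2-fold. Genes of fatty acid oxidation rose in 6 of 23 cases (11 adjusted over the list alone, with 1 lower; median 0.21, or 0.11 with normexp): Cpt1a rose by 1.50 ± 0.05 (n = 3 and 3), Acaa2, the mitochondrial thiolase, by 0.95 ± 0.06, and the carnitine carrier Slc25a20 by 0.76 ± 0.06. Fatty acid synthesis genes fell in 4 of 15 cases (6 adjusted over the list alone; median -0.15), with Scd1 at -1.59 ± 0.08 and Scd2, another desaturase, at -0.74 ± 0.08. Sterol synthesis genes fell in 3 of 20 cases (9 adjusted over the list alone; median -0.19), including Fdps, farnesyl diphosphate synthase, at -0.56 ± 0.07. Camera called these lists (adjusted p = 1.6e-14, 2.2e-04 and 0.0019), and none held with an estimated correlation (adjusted p = 0.064, 0.49 and 0.49). The sterol call was also lost in the matrix values. Outside the lists Fbp2, a gluconeogenic phosphatase, rose by 1.54 ± 0.10 and Cxcl12, a chemokine, by 1.00 ± 0.09.

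Of the 22 ISR genes 0 passed limma's test with oleate, over all genes or adjusted over the list alone: Atf3 changed by 0.06 ± 0.09, Trib3 by 0.14 ± 0.08 and Ddit3 by 0.18 ± 0.07. The list's median of 0.06, which turned to -0.01 with spike-in scaling, was called higher by camera (adjusted p = 0.0057), a call lost without untreated replicate 2 (0.16), in the series matrix values and with an estimated correlation (adjusted p = 0.49), within a range of 8.4e-04 to 0.49. Oxidative phosphorylation genes had a median of -0.10 (-0.03 with quantile normalization) with 0 calls over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.49 with an estimated correlation; lost with normexp, with quantile normalization and in the matrix values). At an unadjusted p under 0.05, 3459 entries differed with oleate. The count of 178 was 74, 93 and 59 without untreated replicates 1, 2 and 3. It was 22, 30 and 42 without oleate replicates 1, 2 and 3, and 99 and 105 without palmitate replicates 1 and 2. The share of higher calls was 50.6% with quantile normalization, 53.2% with normexp and 70.1% in the matrix values. With spike-in scaling, which moved every gene by -0.07, only 3 genes were called, 66.7% of them higher. With palmitate replicates 1 and 2 left out of the shared fit, 40 entries changed.

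Both fatty acids were compared with the same untreated arrays. Of the entries tested in both, 54 were higher with each (5.13 for independent lists) and 64 lower (13.6), and 26 went in opposite directions. Over all genes, 66.2% of the changes had the same sign and they correlated at 0.53. In 100 simulations of unchanged groups with shared controls these were 66.7% and 0.50, values that such groups give whatever their spread. These 2 measures therefore do not show that shared controls made the agreement. The covariance was 0.0645 against 0.0312 simulated, and in a simulated set 0 entries were called higher with both. The untreated arrays are too few to split, and part of the excess may come from the shared controls.

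Palmitate, a saturated fatty acid, and oleate, a monounsaturated one, were compared directly at the same dose and time. ISR genes were higher with palmitate in 18 of 22 cases (19 adjusted over the list alone; median 0.83), with Atf3 at 2.56 ± 0.09 and Trib3 at 1.25 ± 0.08. The amino acid list (17 of 22 higher, 18 adjusted over the list alone; median 0.59) and the aminoacyl-tRNA synthetases (11 of 20, 14 adjusted over the list alone; median 0.32, and 0.03 in the series matrix values) were higher too, and Cth, which rose with palmitate and fell with oleate, differed by 3.01 ± 0.05. Sterol synthesis genes were higher in 15 of 20 cases (17 adjusted over the list alone, with 1 lower; median 0.72): Fdps differed by 1.34 ± 0.07. Fatty acid synthesis genes were higher in 10 of 15 cases, the same adjusted over the list alone (median 0.46), and the largest difference in that list was Scd1, at 2.64 ± 0.08. Camera's adjusted p for these lists was 9.5e-17, 3.4e-17, 1.8e-08, 1.5e-15 and 2.4e-07, and 0.017, 0.010, 0.010, 0.026 and 0.081 with an estimated correlation, so the last call was lost. In the series matrix values the ISR, amino acid, sterol and fatty acid synthesis medians were 0.53, 0.31, 0.43 and 0.17.

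Where the difference between the fatty acids did not pass, the 95% interval limits it. Among fatty acid oxidation genes Acaa2 differed by 0.07 (-0.07 to 0.21). Slc25a20 differed by 0.20 (0.07 to 0.33 unadjusted, limma adjusted p = 0.056) and Ucp2, an uncoupling protein, by 0.31 (0.11 to 0.51 unadjusted, adjusted p = 0.052). Cpt1a was higher with palmitate by 0.20 ± 0.05. That call was lost when most single arrays were left out, and its direction turned to -0.07 in the series matrix values. Of 23 such genes 2 were higher and 1 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.95). Within the ISR list Ddit4 differed by 0.00 (-0.22 to 0.23) and Gdf15 by -0.08 (-0.46 to 0.31). Ins1 differed by 0.11 (-0.10 to 0.33) and Ins2 by 0.16 (-0.10 to 0.43).

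**Figure D3:**
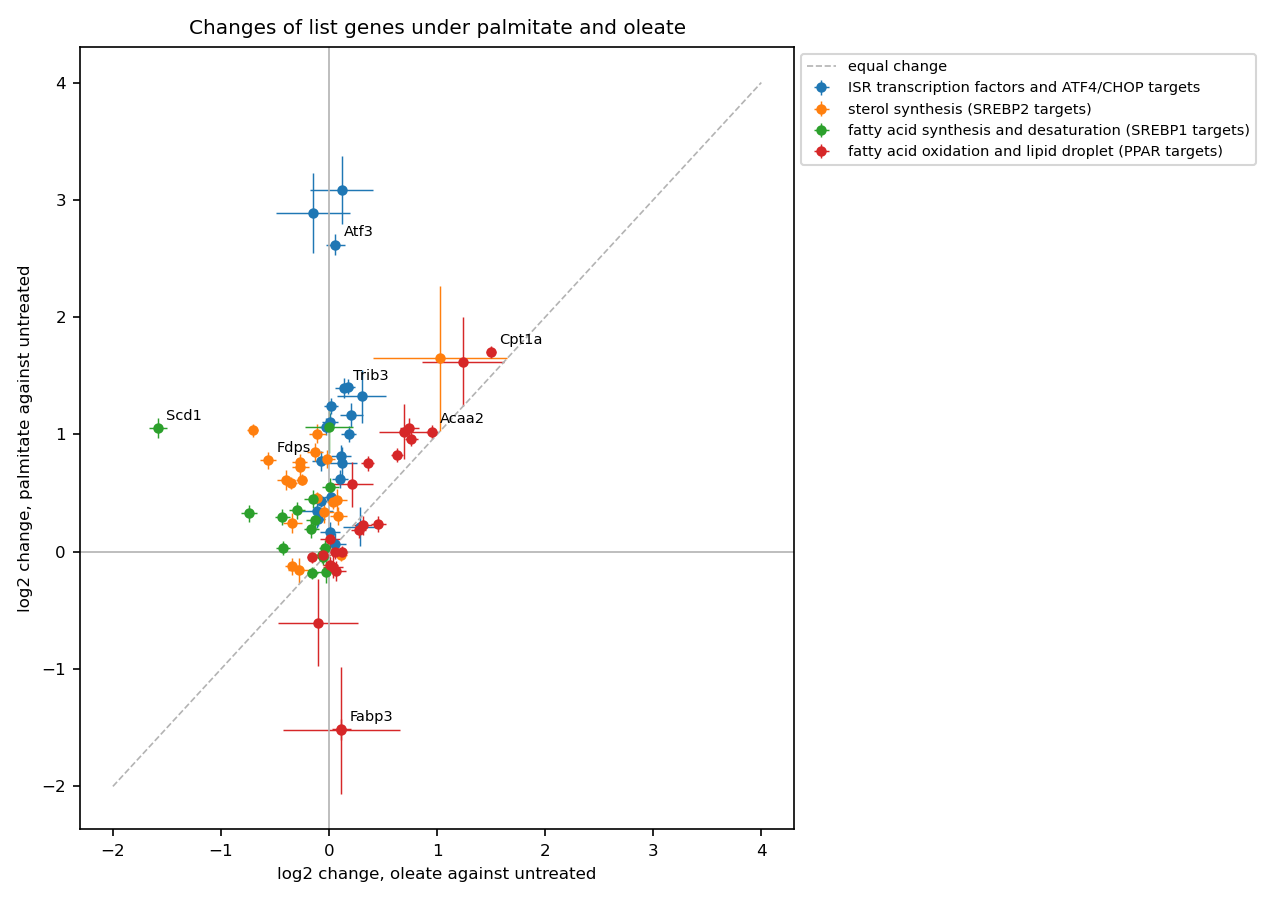
Log2 change with palmitate (vertical axis) against log2 change with oleate (horizontal axis), both relative to untreated cells, for the genes of 4 lists; each point is 1 gene, bars are standard errors, the dashed line marks equal change, and for genes dim in a group the fitted value is drawn, not a bound. Cpt1a lies near the line at 1.70 and 1.50, Scd1 at 1.05 and -1.59, and Atf3 at 2.62 and 0.06; the median of the fatty acid oxidation list with palmitate, 0.19, turns to -0.04 in the series matrix values.

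In total 2922 entries differed between palmitate and oleate, 1589 higher (54.4%) and 1333 lower, 221 at least 2-fold. The count was 1398, 1441 and 1867 without oleate replicates 1, 2 and 3, 1794 without palmitate replicate 1, and 1408 with palmitate replicates 1 and 2 left out. The share of higher calls was 35.9% in the matrix values, which moved the median of all genes by -0.29, and 90.8% with spike-in scaling, which raised every gene, and so every list median, by 0.19. Both left far fewer calls. Cell cycle genes were lower in 10 of 23 cases (13 adjusted over the list alone; median -0.22, or -0.51 in the matrix values and -0.04 with spike-in scaling), with Ccnd2, a D-type cyclin, differing by -0.76 ± 0.05. The p53 targets were higher in 6 of 12 cases (8 adjusted over the list alone, with 3 lower; median 0.36, or 0.07 in the matrix values) and apoptosis regulators in 4 of 16 (9 adjusted over the list alone; median 0.16, -0.12 in the matrix values). Camera's adjusted p was 2.5e-07, 9.4e-04 and 9.4e-04, and 0.081, 0.091 and 0.035 with an estimated correlation. ER chaperones (7 of 26 higher; median 0.12), NF-kB genes (4 higher and 1 lower of 10, 5 and 1 adjusted over the list alone; median 0.31), NRF2 targets (4 and 1 of 16; median 0.11) and exocrine markers (2 of 4; median 0.33) passed camera (adjusted p = 0.0041, 0.0082, 0.016 and 0.0044) and not with an estimated correlation (adjusted p = 0.19, 0.081, 0.19 and 0.081), and the first 3 medians turned to -0.17, -0.01 and -0.18 in the matrix values, where these 3 calls were lost too. Slc2a2 differed by -1.86 ± 0.21. The beta cell list did not pass (6 of 30 lower and 1 higher, 7 and 1 adjusted over the list alone; adjusted p = 0.058), though it did with quantile normalization and with normexp, and its median turned to 0.12 with spike-in scaling. The heart muscle genes Tnnt2 and Tnni3 were at least 35.1-fold and 37.3-fold lower with palmitate than with oleate.

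Fv2E-PERK mock cells were compared with wild-type mock cells to measure how the 2 kinds of cells differ without AP20187. Any other difference between them enters this comparison beside the introduced kinase. They differed in 4677 entries, 2159 higher (46.2%) and 2518 lower, 1113 at least 2-fold. Nrn1, a neurite-promoting protein, was higher by 5.31 ± 0.18 (n = 2 and 2), the homeobox gene Rhox5 by 5.16 ± 0.12, and Magea5 and Magea8, of a germline antigen family, by at least 17.9-fold and 22.9-fold. Wnt4, a signalling ligand, was at least 4.98-fold lower. The hormone genes Sst, somatostatin, and Gcg, glucagon, were higher by 4.18 ± 0.15 and 1.31 ± 0.08. Of 12 immediate early genes 5 were higher (6 adjusted over the list alone; median 0.29), including Egr1 at 2.12 ± 0.21 and Fos at 1.63 ± 0.14. Of 23 cell cycle genes, 9 were higher and 1 lower (16 and 1 adjusted over the list alone; median 0.29), and 8 of 20 sterol genes were higher (10 adjusted over the list alone; median 0.23). The ISR list did not pass (3 higher and 3 lower of 22, 3 and 4 adjusted over the list alone; adjusted p = 0.88), though Atf3 was higher by 0.61 ± 0.08. Camera called the immediate early, cell cycle, sterol, NF-kB (5 of 12 higher, 6 adjusted over the list alone) and other islet endocrine lists (3 higher and 1 lower of 8; adjusted p = 3.6e-04, 2.4e-06, 3.4e-04, 0.0018 and 0.025), and none with an estimated correlation (adjusted p = 0.20, 0.20, 0.40, 0.19 and 0.20). The NF-kB call was also lost with the stricter filter, and the other islet endocrine call without wild-type mock replicate 1 (0.077) or Fv2E-PERK mock replicate 2 (0.065), within a range of 7.6e-05 to 0.20. The 2 groups lay on different slides, wild-type mock on slide 3 and Fv2E-PERK mock on slide 4, so slide and genotype cannot be told apart. The count was 2864 and 3038 without wild-type mock replicates 1 and 2, and 2644 and 2766 without Fv2E-PERK mock replicates 1 and 2. The share of higher calls was 76.2% with spike-in scaling, which raised every gene by 0.13 and left far fewer calls.

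AP20187 was added to Fv2E-PERK cells to follow the genes downstream of an activated PERK kinase over time. Atf3 had risen by 5.58 ± 0.08 at 6 h (n = 2 and 2) and stood 6.52 ± 0.08 above mock at 48 h. Trib3 had risen by 2.65 ± 0.12 and 3.28 ± 0.12, and Ddit3 by 0.57 ± 0.08 and 1.62 ± 0.08. Of 22 ISR genes 16, 15, 16 and 16 were higher at 6, 12, 24 and 48 h and 3, 3, 2 and 4 lower, the same adjusted over the list alone, with medians of 1.08, 1.26, 1.75 and 1.54. With dim genes at their bounds the medians were 1.40, 1.51, 1.78 and 1.48, and with spike-in scaling 1.74, 1.99, 2.68 and 2.12. Amino acid genes were higher in 18, 18, 19 and 20 of 22 cases and lower in 2, 2, 1 and 1, with 3 lower at 12 h adjusted over the list alone (medians 1.13, 1.11, 1.60 and 1.44, or 1.80, 1.84, 2.53 and 2.03 with spike-in scaling), with Cth at 3.52 ± 0.14 and Phgdh, the entry enzyme of serine synthesis, at 2.45 ± 0.15 at 24 h. Of 20 aminoacyl-tRNA synthetases 14, 16, 17 and 17 were higher and 2, 3, 1 and 1 lower, the same adjusted over the list alone (medians 0.75, 0.92, 1.37 and 0.90, or 1.42, 1.65, 2.30 and 1.48 with spike-in scaling). Camera called all 3 lists at each time (adjusted p = 1.1e-05, 2.1e-06 and 4.3e-05 at 6 h and 1.2e-05, 1.2e-07 and 5.2e-06 at 48 h). None held with an estimated correlation (adjusted p = 0.23 for each at 6 h, 0.24 at 12 h, 0.16 at 24 h, and 0.29, 0.26 and 0.26 at 48 h).

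Immediate early genes were the most raised list by the median at each time on this scale, though not at 48 h with normexp, where their median was 1.32 against 1.50 for amino acid genes and 1.38 for ISR genes, nor there with the stricter filter or every probe as its own entry: 10, 10, 11 and 9 of 12 were higher and 0, 0, 0 and 1 lower, with 1 lower at 12 h adjusted over the list alone, and medians of 2.84, 2.72, 2.37 and 1.74, or 3.51, 3.45, 3.30 and 2.32 with spike-in scaling. At 6 h Egr4 and Egr2, zinc finger transcription factors, had risen by 6.57 ± 0.12 and 6.16 ± 0.22, and Egr1 by 4.09 ± 0.21. NF-kB and chemokine genes were higher in 9, 10, 9 and 10 of 12 cases, with 2 lower at each time, and 10 higher at 6 h adjusted over the list alone. Their medians were 1.95, 1.88, 1.42 and 0.62, or 1.63, 1.66, 1.23 and 0.64 with dim genes at their bounds, 1.11, 1.09, 0.68 and 0.41 with normexp, and 2.61, 2.61, 2.36 and 1.21 with spike-in scaling. Cxcl10 was at least 19.6-fold higher at 6 h and Relb had risen by 4.26 ± 0.07. Both lists passed camera at each time (adjusted p = 1.5e-06 and 1.1e-05 at 6 h, 3.2e-04 and 0.0015 at 48 h), with adjusted p from 0.085 to 0.23 and from 0.051 to 0.12 with an estimated correlation. Cell cycle and apoptosis genes passed at 6 and 12 h (12 and 11 of 23 and 8 and 8 of 16 higher, the same adjusted over the list alone; adjusted p = 0.0051, 0.013, 0.040 and 0.043; 0.23, 0.27, 0.18 and 0.19 with an estimated correlation). The apoptosis calls were close to the threshold and were also lost with quantile normalization (0.073 and 0.057) and spike-in scaling (0.11 and 0.063), at 6 h without 6 h replicate 1 (0.069) and at 12 h without 6 h replicate 1 or 2 or 12 h replicate 2 (0.052, 0.052 and 0.053), within ranges of 1.7e-05 to 0.18 and 4.4e-06 to 0.19. At 24 h neither list passed (0.13 and 0.052), but both did with normexp (0.037 and 0.014) and with no filter on dim probes. With fry included, as in the ranges at 6 and 12 h, the adjusted p at 24 h ran from 3.4e-04 to 0.47 and from 6.2e-07 to 0.16. At 6 and 12 h the medians were 0.29 and 0.20 for cell cycle and 0.37 and 0.28 for apoptosis genes. With dim genes at their bounds or left out, those of the apoptosis genes were 0.34 and 0.20. Members of the 2 lists included Mcm5, a replication helicase subunit, at 1.30 ± 0.08 and Txnip, a thioredoxin-binding protein, at 2.34 ± 0.14, both at 6 h. Not all members rose: Bid, a death agonist, changed by -0.97 ± 0.10 at 6 h.

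Beta cell identity genes fell in 26, 26, 26 and 22 of 30 cases and 1 rose at each time, or 2 at 24 h adjusted over the list alone, with medians of -0.78, -1.02, -1.06 and -0.98, or -0.48, -0.55, -0.73 and -0.61 with quantile normalization. With genes dim in both groups left out the medians at 6 and 12 h were -0.71 and -0.98. With spike-in scaling they were -0.12, -0.29, -0.13 and -0.39. G6pc2, the islet glucose-6-phosphatase subunit, fell by 2.65 ± 0.11 at 6 h, and Isl1 and Pax6, islet transcription factors, by 2.29 ± 0.11 and 1.78 ± 0.09 at 48 h. Ins1 fell by 0.63 ± 0.11 and Ins2 by 0.37 ± 0.13 at 6 h, but these values turned to 0.03 and 0.29 with spike-in scaling, and that of Ins2 to 0.19 with quantile normalization. Glycolysis genes fell in 13, 13, 13 and 12 of 14 cases (medians -1.24, -1.79, -1.72 and -1.83, or -0.57, -1.07, -0.79 and -1.25 with spike-in scaling), including Ldha, lactate dehydrogenase, by 3.50 ± 0.11 and Pdk1, pyruvate dehydrogenase kinase, by 4.01 ± 0.09 at 48 h. Fatty acid synthesis genes fell in 13, 15, 14 and 14 of 15 (medians -0.69, -0.99, -0.95 and -0.67; 1 rose at 48 h adjusted over the list alone), and with spike-in scaling the medians were -0.02, -0.26, -0.02 and -0.08, with Scd2 at -2.09 ± 0.11 at 24 h. The 3 lists passed camera at each time (at 24 h adjusted p = 5.0e-06, 1.9e-05 and 6.5e-05), and not with an estimated correlation (adjusted p from 0.051 to 0.094, 0.13 to 0.21 and 0.24 to 0.34).

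ER chaperone genes fell in 24, 23, 17 and 15 of 26 cases and 1, 1, 3 and 4 rose (2 rose at 6 h and 18 fell at 24 h adjusted over the list alone). The medians were -0.95, -0.90, -0.52 and -0.32, but with spike-in scaling they were -0.29 and -0.17 at 6 and 12 h and turned to 0.42 and 0.27 at 24 and 48 h. The disulfide isomerase Pdia6 fell by 1.54 ± 0.15 and the chaperone Calr, calreticulin, by 1.44 ± 0.09 at 6 h (camera adjusted p = 1.1e-05, 1.9e-05, 0.017 and 0.042; 0.23, 0.24, 0.47 and 0.56 with an estimated correlation). The call at 24 h was lost with quantile normalization (0.075), normexp (0.057), no filter on dim probes (0.053) and spike-in scaling (0.29), within a range of 2.2e-04 to 0.47. The call at 48 h was lost without Fv2E-PERK mock replicate 1 (0.094), without 48 h replicate 1 (0.063), within slide 3 (0.092), with quantile normalization (0.58), normexp (0.49), no filter (0.23), the stricter filter (0.15) and spike-in scaling (0.23), within a range of 0.0011 to 0.58.

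Oxidative phosphorylation genes fell in 18, 17, 16 and 16 of 20 cases (18 at 12 h adjusted over the list alone). Their medians were -0.65, -0.66, -0.63 and -0.59, and turned to 0.01, 0.07 and 0.31 at 6, 12 and 24 h with spike-in scaling, with Ndufa1, a subunit of complex I, at -1.44 ± 0.10 at 6 h. Camera gave adjusted p = 1.9e-04 at 6 h and 8.7e-04 at 48 h, lost with quantile normalization (0.29 and 0.32, and at the other times too, with medians of -0.10, -0.18, -0.23 and -0.16) and with an estimated correlation (adjusted p = 0.29 and 0.38). With fry included, the ranges of adjusted p were 1.9e-05 to 0.29 and 6.5e-05 to 0.38. NRF2 targets passed at 6 and 12 h (12 of 16 lower each, the same adjusted over the list alone; adjusted p = 0.0048 and 0.0078; 0.11 and 0.13 with an estimated correlation), with Nqo1 lower by a log2 change of -1.67 ± 0.10 at 6 h. Sterol synthesis, fatty acid oxidation, interferon-stimulated, p53, other islet endocrine, exocrine, and mesenchymal, endothelial and immune lists did not pass at any time. Their adjusted p was lowest for sterol synthesis at 12 h (0.068), when 13 of 20 were lower, and that list did pass with quantile normalization (0.032) and without Fv2E-PERK mock replicate 2 (0.041), within a range of 4.1e-04 to 0.56. Within them Cd36, a fatty acid transporter, was at least 14.5-fold higher at 12 h, and Plin2, a lipid droplet coat protein, rose by 2.92 ± 0.08 at 48 h.

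**Figure D4:**
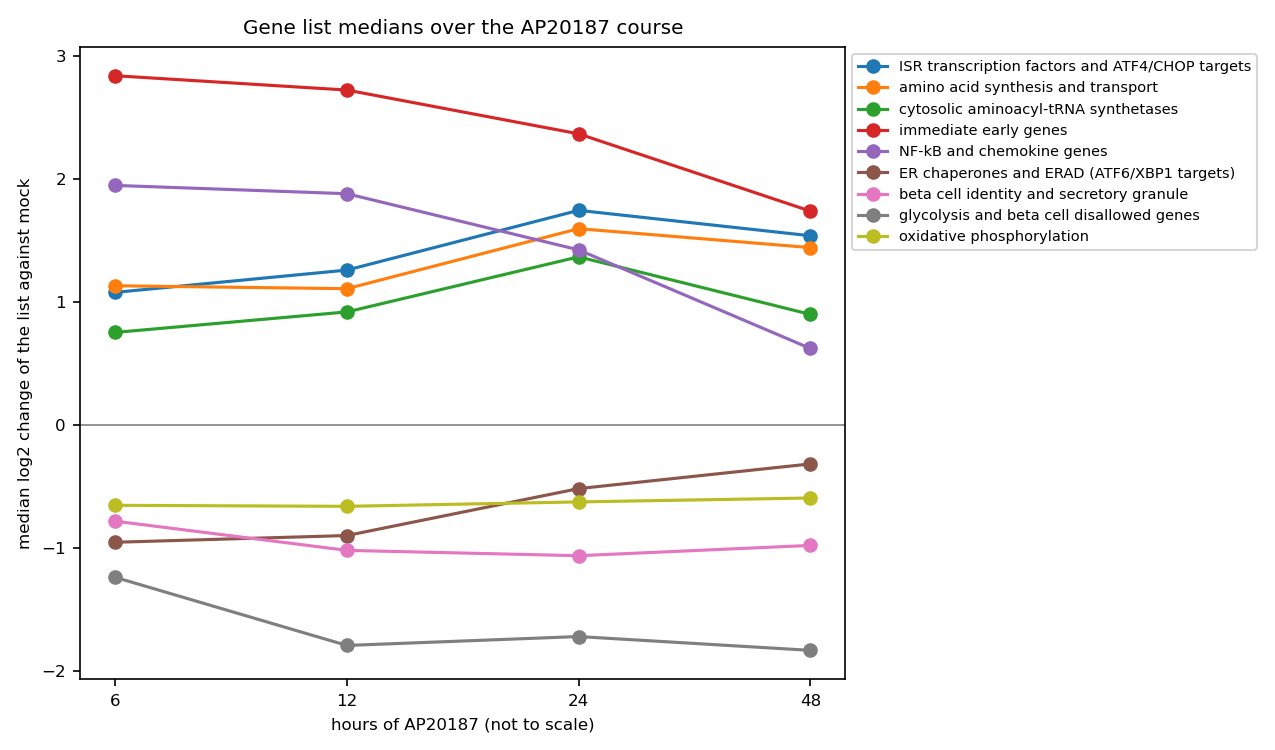
Median log2 change against mock (vertical axis) of 9 gene lists at 6, 12, 24 and 48 h of AP20187 (horizontal axis, not to scale); each point is 1 list at 1 time, joined by lines. Immediate early genes stand at 2.84 at 6 h and 1.74 at 48 h and glycolysis genes at -1.24 and -1.83; with spike-in scaling the oxidative phosphorylation medians at 6, 12 and 24 h and the ER chaperone medians at 24 and 48 h turn positive.

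The number of entries that changed against mock was 15168, 15822, 15758 and 14456 of 23386 at 6, 12, 24 and 48 h, with 38.4, 40.1, 40.1 and 44.0% higher, and 4475, 5724, 5773 and 4715 changed at least 2-fold. The median of all genes lay at -0.23, -0.19, -0.20 and -0.07. Spike-in probes stood 2.52 to 3.26 log2 units above the 75th percentile on the AP20187 arrays and 3.48 to 3.79 on the Fv2E-PERK mock arrays, and scaling to them raised every gene, and so every list median, by 0.66, 0.73, 0.93 and 0.58. Whether the amount of spike-in per amount of RNA was constant is not known, so neither scale is taken as the right one. With that scaling 89.4, 88.0, 93.5 and 88.4% of calls were higher and 3926, 4111, 5831 and 2901 of the called genes turned direction. All directions given here are therefore relative to the 75th percentile. The share of higher calls was also 49.0% at 6 h with quantile normalization, which moved the median of all genes by 0.12 at 6 h and 0.11 at 12 h, and 32.6% at 48 h with normexp. Among the largest changes, Acox2 and Car6 had risen by at least 32.0-fold and by 6.66 ± 0.18 at 24 h, and at 48 h P2rx7, an ATP-gated channel, was at least 106-fold higher. Slc16a3, a lactate exporter, fell by 4.21 ± 0.17 at 6 h and 5.04 ± 0.17 at 48 h. The times share their mock arrays. At 6 and 12 h 5025 entries were higher at both (1579.4 for independent lists) and 8037 lower (3785.4). The changes correlated at 0.90, with 87.7% of the same sign, against 0.50 and 66.7% in 100 simulations of unchanged groups, and their covariance was 0.739 against 0.0299 simulated. At 6 and 48 h 3263 were higher at both (1581.7) and 1879 went in opposite directions, with a covariance of 0.426 against 0.0301 simulated. The correlation was 0.53 and 67.1% had the same sign, against 0.50 and 66.6% simulated. Unchanged groups that share controls give such values whatever their spread, so these 2 measures do not show that shared controls made the agreement. In a simulated set 0 entries were called higher at both times. The mock arrays are too few to split, and part of the excess may come from the shared controls.

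The 48 h and 6 h samples were compared to separate late from early changes. They lay on different slides, as did the 48 h and mock arrays, so part of each difference may come from the slides. Immediate early genes were lower at 48 h than at 6 h in 10 of 12 cases and 1 was higher (median -1.49), NF-kB genes in 8 of 12 with 1 higher (median -0.89) and cell cycle genes in 16 of 23 with 1 higher (median -0.51). ER chaperones were higher in 18 of 26 (median 0.48). All these counts were the same adjusted over the list alone. Egr1 fell by 1.96 ± 0.21 between the times (n = 2 and 2), Aurka, a mitotic kinase, by 1.47 ± 0.07, and Dnajb9, an ER cochaperone, was higher by 1.72 ± 0.09. Camera gave adjusted p = 0.0012, 0.0048, 5.0e-04 and 0.0016, and adjusted p = 0.31, 0.26, 0.31 and 0.51 with an estimated correlation. The NF-kB call was also lost with the stricter filter and the ER chaperone call with spike-in scaling. In total 14220 entries differed, 7771 higher (54.6%) and 6449 lower. The largest rises included Gpnmb, a lysosomal glycoprotein, at 7.65 ± 0.23, Lcn2, an iron-binding acute-phase protein, at 7.05 ± 0.17 and Lgals3 at 6.83 ± 0.17. Against the wild-type mock arrays of their own slide, a comparison added after seeing the data, 80.5% of the genes called at 48 h kept the call and direction and 298 were called in the opposite direction. Among named genes Sst, Eya2 and Ptgds turned, to 3.22, 0.14 and 2.34. With the arrays of slide 4 alone, 94.1, 94.6 and 94.4% of the calls at 6, 12 and 24 h were kept.

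Genes raised by palmitate were set against those raised by AP20187 to ask which saturated fatty acid genes also rise after AP20187. A gene raised by AP20187 need not be an ISR target, since late changes are included and wild-type cells with AP20187 are not analysed here. Of 20987 entries tested in both experiments, palmitate raised 1092 over untreated and over oleate, and AP20187 raised 7126. Both raised 665, against 370.8 for independent lists, a ratio of 1.79 (Fisher's exact test, one-sided p = 6.5e-78). Genes are not independent, so this p is too small. Of the palmitate-raised entries 60.9% were AP20187-raised, against 34.0% of all entries. Lowered entries were shared in 802 cases of 1084 and 10629, against 549.0 (ratio 1.46, Fisher's exact test, one-sided p = 1.8e-58). The AP20187-raised and AP20187-lowered sets are relative to the 75th percentile, and the overlap was not counted with spike-in scaling. That scaling turned the direction of 5831 of 15758 called genes at 24 h and 2901 of 14456 at 48 h. The shared raised genes with the largest smaller changes were Acox2, Car6, Ostn, Akr1b7, Ptgs2, Lgals3, Saa3, Slc7a11, Anxa10 and Fgf21, whose change with palmitate turned to -5.38 in the series matrix values: at 48 h of AP20187 Car6 had risen by 7.87 ± 0.18, Lgals3 by 7.10 ± 0.17 and Anxa10 by 6.67 ± 0.27. Of the shared lowered genes, C1qa, a complement subunit, fell by 1.61 ± 0.07 with palmitate and by 2.33 ± 0.09 at 48 h, and Trpm5, a cation channel, by 1.30 ± 0.09 and 1.89 ± 0.19.

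The 200 largest AP20187 rises at 6, 12, 24 and 48 h had median changes of 0.17, 0.21, 0.42 and 0.61 with palmitate: 70, 77, 105 and 117 rose and 19, 15, 9 and 6 fell. Camera with an estimated correlation gave adjusted p = 1.2e-04, 1.1e-04, 5.6e-05 and 1.1e-04. With oleate their medians were 0.00, -0.00, -0.02 and 0.02 and at most 1 of the 200 rose. Camera still called them higher with oleate at 6, 12 and 48 h with an estimated correlation (adjusted p = 0.016, 0.0497, 0.30 and 0.039), and at 6 and 48 h with the preset one (0.019, 0.098, 0.35 and 7.3e-04). Between palmitate and oleate the medians were 0.15, 0.20, 0.44 and 0.60. The 200 largest falls at 6, 12, 24 and 48 h had medians of -0.08, -0.07, -0.16 and -0.33 with palmitate, where 31, 33, 55 and 87 fell and 17, 10, 9 and 7 rose. Camera called those at 24 and 48 h lower (adjusted p = 0.997, 0.91, 0.018 and 1.7e-08), and none with an estimated correlation (adjusted p = 0.999, 0.999, 0.52 and 0.30). The 7057 AP20187-raised entries with a value on every array of the fatty acid experiment had a median of 0.01 with palmitate (camera adjusted p = 2.3e-05, adjusted p = 0.053 with an estimated correlation). The 10403 AP20187-lowered ones had a median of -0.09 (camera adjusted p = 4.3e-05, lost with an estimated correlation at adjusted p = 0.32). The shared count of 665 was 106 with at least 2-fold changes, 71 in the series matrix values, and 451 to 681 when single arrays were left out. With the 2-fold threshold and in the matrix values far fewer genes were called with palmitate. The fall of the shared count there therefore does not show how the ratio to independent lists changed.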

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

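The comparisons within slide 3 and between the 2 mock groups and scaling to spike-in probes were chosen after the result was seen. Of the genes reported here, 7 were picked because they changed in opposite directions with palmitate and oleate and the difference passed limma's test. Passing that test was a condition of the pick and is no further result. Cth changed by 2.31 and -0.70, a difference of 3.01 ± 0.05. The desaturases Scd1 and Scd2 changed by 1.05 and -1.59 and by 0.33 and -0.74, differences of 2.64 ± 0.08 and 1.07 ± 0.08, and the elongase Elovl6 by 0.30 and -0.43, a difference of 0.73 ± 0.07. The sterol enzymes Fdps and Mvd differed by 1.34 and 0.94. Ccnd2 went the other way, at -0.32 with palmitate and 0.44 with oleate, a difference of -0.76 ± 0.05. All 7 kept opposite signs with spike-in scaling.

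After AP20187, 22 named genes were picked in the same way, by opposite directions at 6 h and at 48 h against mock. A difference of the times that passed limma's test was again a condition of the pick. Higher at 48 h were the lipid droplet coat Plin2 by 3.82 (-0.90 at 6 h and 2.92 at 48 h), the death agonist Bid by 3.27 (-0.97 and 2.30), the heme oxygenase Hmox1 by 3.08 (-1.01 and 2.07), Ppy by 2.35, Dnajb9 by 1.72, Hyou1, another ER chaperone, by 1.34, Trp53inp1 by 1.34, Bst2 by 1.25, Nos2 by 1.16, Itgam by 1.07 and Cpt1a by 1.00. Lower at 48 h were Btg2, which differed by -1.91, Plin5 by -1.85, Irf1 by -1.73, Aurka by -1.47, Bcl2 by -1.23, Plk1 by -1.09, Casp9 by -1.07, Stat2 by -1.05, Srxn1 by -0.997, Usp18 by -0.66 and Ccne1 by -0.55. Spike-in scaling adds 0.66 to every gene at 6 h and 0.58 at 48 h, so the differences of the times move by only -0.08, but small changes turn sign: 13 of the 22 kept opposite signs and 9 were positive at both times. These were Trp53inp1, Itgam and Cpt1a, now positive at 6 h (0.28, 0.20 and 0.35), and Btg2, Plk1, Stat2, Srxn1, Usp18 and Ccne1, now positive at 48 h (0.20, 0.049, 0.057, 0.13, 0.20 and 0.32). Of the 13 that kept opposite signs, Nos2 at 6 h and Bcl2 and Irf1 at 48 h did so only by small values (-0.0048, -0.020 and -0.090). Another probe of Trp53inp1 was called in the opposite direction at 6 h.

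The 48 h arrays lay on slide 3 with the wild-type mock arrays, and the 6 h and Fv2E-PERK mock arrays on slide 4. A difference between the slides as the whole cause of the changes at 48 h is argued against by the comparison with wild-type mock within slide 3, where 80.5% of the genes called at 48 h were called in the same direction and 298 in the opposite one (94.8% had the same direction at any p, against 53.7% in simulations where only the slides differ and the 48 h arrays are shared). Wild-type mock against Fv2E-PERK mock spans the same slides, and there only 11.4% of the genes called at 48 h were called in the direction that a slide difference needs, which argues against it unless the genotype offset the rest. For single genes, part of the difference may still come from the slides, and both comparisons also hold the difference between Fv2E-PERK and wild-type cells. A later response to the kinase stays open as untested.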

How the results depend on the processing

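Scaling to spike-in probes, leaving out palmitate replicates 1 and 2, leaving out spots in local defects and the fits on 1 slide were chosen after the results were seen. The causes of the differences were not tested. Of the counts, 20 of 21 lay within 1.5 times the reported value with normexp and all 21 with quantile normalization, all arrays in 1 fit or the stricter filter. With normexp, oleate changed 94 genes. In the series matrix values, which leave dim probes blank and scale the fatty acid arrays by other constants, palmitate changed 549 genes against untreated and 409 against oleate, and 71 raised genes were shared between the experiments. Without the filter on dim probes the counts were 2266, 26 (oleate), 1398 and 398. With only the 2 groups compared in the fit, which leaves fewer arrays, they were 2598 for palmitate, 40 for oleate and 1339 for Fv2E-PERK against wild-type mock. With a variance trend and robust prior oleate changed 354 genes. At a change of at least 2-fold, a stricter threshold, the counts were 286, 9 and 221 for palmitate, oleate and their difference, 4475, 5724, 5773 and 4715 at 6, 12, 24 and 48 h, 4501 at 48 h against 6 h, 1113 for the genotype and 106 shared. Of the list calls over all contrasts, 88 with camera, 9 held with an estimated correlation and fry, which compares no list with other genes, made 133. Without palmitate replicates 1 and 2, which leaves 1 palmitate array, the counts were 1719, 40, 1408 and 274 shared. With spike-in scaling palmitate changed 649 genes, oleate 3, palmitate against oleate 773, 48 h against 6 h 8429 and the genotype 1418. With replicate number as a block, oleate changed 54 genes, and palmitate 3603. Deviations of same-numbered arrays from their group means had correlations of -0.03 to 0.04 in the fatty acid and -0.01 to 0.13 in the PERK experiment. In the latter most were positive, so a weak link between same-numbered arrays is not excluded. The numbers were not taken to pair the arrays because nothing in the labels says that they mark a shared culture.

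With quantile normalization Ins1 turned to 0.0896 at 6, 12 and 48 h, a value fixed by the method since its probe ranked 1 or 2 on every array of that experiment, and Ins2 to 0.19, 0.18, 0.14 and 0.39 at 6, 12, 24 and 48 h. In the matrix values the glycolysis list with oleate turned by camera's direction (median -0.0113), Fgf21 with palmitate to -5.38, and Cpt1a between the fatty acids to -0.0681. Within slide 3, Sst, Eya2 and Ptgds turned to 3.22, 0.14 and 2.34 at 48 h. When single arrays were left out, palmitate changed 2670 to 3713 genes against untreated and 1398 to 3155 against oleate, and oleate 22 to 139. AP20187 changed 12893 to 15541, 13828 to 16156, 13778 to 15832 and 11937 to 14901 at 6, 12, 24 and 48 h, and 19039 to 20279 by the F test, against 20315. The genotype changed 2644 to 5166, 48 h against 6 h 11434 to 14642, shared raised genes were 451 to 681, and 85 to 91 list calls were made. Oleate gave 74, 93 and 59 genes without untreated replicates 1, 2 and 3, 22, 30 and 42 without oleate replicates 1, 2 and 3, and 99 and 105 without palmitate replicates 1 and 2. Palmitate gave 2670 against untreated without palmitate replicate 1, and against oleate 1794 without it and 1398, 1441 and 1867 without oleate replicates 1, 2 and 3. The genotype gave 2864 and 3038 without wild-type mock replicates 1 and 2 and 2644 and 2766 without Fv2E-PERK mock replicates 1 and 2. Where a lone array stood for a group, it is assumed to vary like the others. Palmitate replicate 3 was also alone on slide 2, so without replicates 1 and 2 slide and palmitate cannot be told apart. Dim signals limit the values: where a gene was above background on no array of a group, only a bound on its change is known.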

Other observations

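The test of the heart muscle genes against the wild-type mock arrays was chosen only after the result was seen, as was the comparison within slide 3. At 48 h of AP20187, 7 of 23 cell cycle genes rose and 12 fell, and the list did not pass (camera adjusted p = 0.31; median -0.26, which turned to 0.32 with spike-in scaling): the replication helicase gene Mcm2 rose by 1.41 ± 0.08 (n = 2 and 2), while the mitotic gene Birc5 fell by 1.19 ± 0.08 and Aurkb, a mitotic kinase, was at least 4.77-fold lower. Hrk, a death agonist, was at least 58.8-fold higher and Bbc3, which encodes PUMA, rose by 1.65 ± 0.08, while Bik, another member of that family, fell by 1.52 ± 0.09, a call lost within slide 3. Ifit2, an interferon-stimulated gene, fell by 1.40 ± 0.11. Ghrl, which encodes ghrelin, rose by 1.95 ± 0.22, and Nqo1 fell by 2.53 ± 0.10 where Hmox1, another NRF2 target, rose by 2.07 ± 0.08.

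Without AP20187, Fv2E-PERK cells had higher Slc38a1, a glutamine transporter, by 2.98 ± 0.18 (n = 2 and 2), higher Spp1 by 2.13 ± 0.26 and higher Hmgcs1, an early enzyme of sterol synthesis, by 1.38 ± 0.08 than wild-type cells. Krt7, a duct keratin, differed by -1.68 ± 0.10, and Ucn3, a marker of mature beta cells, was at least 2.35-fold lower. The wild-type mock arrays lay on slide 3 and the Fv2E-PERK mock arrays on slide 4, so genotype and slide cannot be told apart in these values.

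Skeletal muscle genes were bright on palmitate replicates 1 and 2. Myh4 and Acta1, abundant in fast muscle, had signals of 2.08 and 2.26 on replicate 1 and 2.12 and 2.40 on replicate 2, against -7.11 and -1.12 on replicate 3. The palmitate treatment is argued against, since replicates 1 and 2 lay above replicate 3, treated alike, by a median of 3.84 over 20 other skeletal muscle genes (lower quartile 2.38). A candidate explanation is RNA of skeletal muscle mixed into those 2 samples, which needed most of the 20 genes to be present: 18 were well above background on both arrays, against 8 on replicate 3. Of these genes, 12 were well above background on at least 1 array of the PERK experiment and 7 on both wild-type mock arrays, and where such RNA would have come from was not tested.

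Heart muscle genes were bright on the 6 untreated and oleate arrays and far lower on the palmitate arrays. Mean signals were 2.38 and -3.39 for Myl2 and 1.53 and -4.85 for Myh6. Of the palmitate arrays, Myl2 was still well above background on 2 and Myh6 on 1. RNA of heart muscle mixed into the 6 samples and an effect of palmitate cannot be told apart here. Of 16 other heart genes 4 were well above background on all 6 arrays, with a median difference of 0.37 from the palmitate arrays, which met the bound set against mixed RNA beforehand, but 8 were well above background on none of the 9 arrays, and genes that dim exclude nothing, a reading made after the result was seen. The 4 genes, Ankrd1, Casq2, Tnnc1 and Smyd1, were higher by 3.67, 3.15, 1.28 and 0.08 than on the palmitate arrays. The 9 heart genes seen first lay a median of 5.73 higher on the untreated arrays than on the wild-type mock arrays (lower quartile 5.44). Neither group received palmitate, so samples of the 2 experiments differed in these genes without it. Whether the cells differed or other RNA was mixed in is not settled by this. That palmitate lowers these genes where they are present is left open too.

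On untreated replicate 2, 50% of 232 probes inside local tiles deviated from the other untreated arrays by over 1 log2 unit, a share partly fixed by how the tiles were chosen, against 0.253% of 396 probes of the same genes outside. Splitting the 6 arrays of each fatty acid comparison into 3 and 3 gives 10 splits, so the share of splits with as many genes is never under 0.1. In each comparison 1 split, the real one, gave its count of 4267, 178 or 2922 genes, and the highest of the others gave 0.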
